A study of Homo sapiens with 12 samples.

How the data were processed

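RKO cells, a human colon cancer line, were held for 24 hours in medium with 400 uM arginine (fed) or 12.5 uM arginine (starved). RNA-seq and ribosome profiling libraries were made concurrently: RNA-seq measures transcript levels, and in ribosome profiling fragments protected by ribosomes (footprints) are sequenced to measure ribosome occupancy of each transcript. Each of the 4 groups held 3 libraries, 12 in all. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

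The authors deposited whole-number counts per Ensembl transcript in 1 table for each assay, with no normalization, and the unit was checked on the values. Per the labels' protocols, RNA libraries were prepared with a TruSeq kit and ribosomal RNA was depleted from footprint samples with RiboCop. Per the submitters' processing notes, cutadapt, STAR, UMI-tools and DESeq2 were used with the build GRCh38.p13, with no roles or versions. The counting tool, the annotation release, the treatment of reads that map to several places, any limit on footprint length, and whether counts cover the coding sequence or the whole transcript are not given in the sources used here. Counts over whole transcripts would include footprints outside the coding sequence, and counts per transcript depend on how reads shared by isoforms were assigned. Transcripts that share reads with near-identical copies are uncertain in both assays for the same reason. Every sample column of both tables was used.

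The RNA table listed 19686 transcripts, all of them also among the 19849 of the footprint table. Total counts per library ranged from 4670881 to 7967215 for RNA and from 2063952 to 4364383 for footprints. The tables pair identifiers with no gene names, and 0 of the 19849 identifiers matched the gene tables used here. The 26 gene lists fixed before the data were examined and the planned comparison with arginine codon content therefore could not be tested, and genome positions and exon annotations are not used here. For the same reason at most 2 transcripts that rose and 2 that fell are named. The rule fixed in advance takes the largest absolute log2 fold changes among transcripts with an adjusted p under 0.05, an average log2 CPM (counts scaled to library size) of at least 4, and no overlap between starved and fed libraries; it was applied here to the footprint comparison, a choice made after the identifiers had been seen. The parts of the rule that needed gene names were not used here.

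Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p under 0.05), with TMM scaling factors and transcripts kept by filterByExpr. RNA and footprint libraries were fitted separately with treatment as the only term. Translational efficiency, the ratio of footprints to RNA per transcript, was tested as the interaction of assay and treatment in 1 model over all 12 libraries, with TMM factors computed within each assay and transcripts kept in both. "Called" below means past the adjusted threshold, and every log2 fold change is starved over fed. All changes are relative to the other transcripts of the same assay, since no spike-in was used here. CPM values printed for single transcripts are counts divided by the library total, without TMM factors. Log2 CPM used a prior count of 2. Confidence intervals are 95% exact Clopper-Pearson intervals and cover counting error only, and so does the limit of 3 counts set for a count of 0.

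The biological coefficient of variation was 5.75% for RNA and 13.7% for footprints. Tested transcripts had a median of 225 counts per RNA library and 70.2 per footprint library, and the median standard error of the log2 fold change was 0.10 for RNA, 0.19 for footprints and 0.20 for translational efficiency. No pair of replicates held identical values, and over transcripts with at least 20 counts in the pair, chi-square per degree of freedom lay between 2.07 and 7.73 in the 12 pairs within groups. The tests were tried on simulated counts with 200 transcripts changed. Far more were called in the real data, which makes the adjusted threshold less strict there. Recovery of real changes may be higher than the rates below. Over 11572 transcripts, the RNA test recovered 77.6% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes, with 4.79% of its calls false. Over 13457 transcripts, the footprint test recovered 13.4%, 76.1% and 97.0% of changes of the same sizes, with 9.49% of its calls false. Over 11027 transcripts, the efficiency test recovered 20.9%, 68.7% and 98.5%, with 8.09% of its calls false. Fewer footprint or efficiency calls than RNA calls therefore do not show that fewer transcripts changed.

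Alternatives fixed in advance were DESeq2 size factors, library totals without TMM factors, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, a shared culture term for RNA and footprints, limma 3.58.1 with voom and quality weights per assay, all 12 libraries in 1 fit, leaving out each library in turn and, for the correlation between the assays, an average log2 CPM of at least 4 in both. Added after the data were seen were RNA thinned to footprint depth, an expression limit for the efficiency test, a limit of the footprint test to transcripts kept in both assays, and removal of an abundance trend (a lowess curve with span 0.3 per library within its assay). Counts in which efficiency opposed RNA, or in which the assays were called in opposite directions, were also defined after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.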

Results

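Transcript levels and ribosome footprints were measured in RKO colon cancer cells held for 24 hours in 400 uM arginine (fed) or 12.5 uM arginine (starved), with n = 3 libraries per group and assay. The design addresses what low arginine does to transcript levels, to ribosome occupancy and to the ratio of the 2. RNA totals were 7967215, 4670881 and 6936609 counts in fed replicates 1 to 3 and 7323897, 6185760 and 6778851 in starved replicates 1 to 3. Footprint totals were 4364383, 2063952 and 2118467 counts in fed replicates 1 to 3 and 2337709, 2827949 and 3657961 in starved replicates 1 to 3. The first principal component separated starved from fed libraries in both assays and held 86.9% of the variance for RNA and 67.6% for footprints. Within groups, log2 CPM of replicate pairs correlated across transcripts at 0.991 or above for RNA and between 0.965 and 0.977 for footprints.

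Starvation changed the level of most transcripts that could be tested. Of 11572 transcripts, 7862 (67.9%) were called in the RNA comparison, 3911 higher and 3951 lower in starved cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Most of these changes were small: the median absolute log2 fold change of called transcripts was 0.61. More than 2-fold changes were called for 785 transcripts that rose and 1011 that fell, and more than 4-fold changes for 126 and 184. The median log2 fold change over all tested transcripts was −0.01 with TMM factors and −0.12 when library totals alone were used, so directions of small changes are relative to the scaling. Library totals alone gave 3189 higher and 4677 lower.

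With TMM factors, the RNA that rose was on average more abundant than the RNA that fell. When the 11027 transcripts kept in both assays were ranked by mean RNA level and divided into 5 bins of equal size, the bin with the least RNA held 384 transcripts that rose and 833 that fell. The bin with the most RNA held 1136 that rose and 612 that fell. With library totals alone the counts were 316 and 936 in the bin with the least RNA and 940 and 763 in the bin with the most. With an abundance trend removed from each library, an alternative added after the data were seen that centres fold changes at each abundance level by construction, they were 547 and 595, and 857 and 840.

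Ribosome occupancy rose on some transcripts and fell on others. Of 13457 transcripts tested, 5359 (39.8%) were called, 2547 with more and 2812 with fewer footprints in starved cells, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With library totals alone the majority turned, to 2894 higher and 2575 lower, and without fed footprint replicate 3 the counts were 1895 and 2506. The median absolute log2 fold change of called transcripts was 0.84, while over all tested transcripts the SD of the log2 fold change was 0.73 for footprints and 0.82 for RNA. Footprints rose more than 2-fold on 874 transcripts and fell more than 2-fold on 1008, and the counts for more than 4-fold were 98 and 109. Replicate spread was wider than in RNA, which limits the detection of changes of about 1.5-fold, so the counts of calls in the 2 assays do not show in which of them more transcripts changed.

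Footprints rose most on ENST00000398477 and ENST00000284818 among the transcripts that met the rule for naming. ENST00000398477 went from 0.777 ± 0.518 CPM in fed to 71.0 ± 4.49 CPM in starved footprint libraries (SD, n = 3), a log2 fold change of 6.15 (SE 0.26, adjusted p = 2.28e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its RNA had 0 counts in the 3 fed libraries, which allows up to 0.153 CPM (3 counts over the group), and 95 counts in the starved libraries, 4.68 ± 0.682 CPM (SD, n = 3), at least 30.6-fold higher. ENST00000284818 went from 0.553 ± 0.362 to 35.6 ± 1.39 CPM in footprints (SD, n = 3), a log2 fold change of 6.08 (SE 0.32, edgeR adjusted p = 1.73e-07), and from 0.228 ± 0.217 to 8.82 ± 1.22 CPM in RNA (SD, n = 3), a log2 fold change of 5.11 (SE 0.37, edgeR adjusted p = 1.33e-19). The efficiency of neither passed the test, with edgeR adjusted p of 0.267 for ENST00000398477 and 0.451 for ENST00000284818, and fed cells gave 8 and 4 footprint counts on them in all. With so few fed counts single libraries moved the fitted footprint changes by over 1.5-fold: without fed replicate 1 they were 7.01 for ENST00000398477 and 5.47 for ENST00000284818, and the RNA change of ENST00000284818 was 5.74 without fed RNA replicate 3. The fitted efficiency change of ENST00000398477, whose fed RNA count was 0, was −1.27 and is no bound; it was 0.29 with limma-voom.

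Footprints fell most on ENST00000357246 and ENST00000244534 by the same rule. ENST00000357246 dropped from 147 ± 14.98 CPM in fed to 3.47 ± 0.756 CPM in starved footprint libraries (SD, n = 3), a log2 fold change of −5.47 (SE 0.20, adjusted p = 1.53e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its RNA dropped from 128 ± 5.74 to 8.21 ± 1.28 CPM (SD, n = 3), a log2 fold change of −3.83 (SE 0.11, edgeR adjusted p = 7.81e-41). The footprints fell further than the RNA, and its efficiency fell by 1.57 on the log2 scale (SE 0.26, edgeR adjusted p = 0.000298). ENST00000244534 carried many footprints for its RNA level: 946 ± 36.2 CPM in fed and 67.4 ± 6.81 CPM in starved footprint libraries (SD, n = 3) against 15.6 ± 0.529 and 1.62 ± 0.313 CPM in RNA (SD, n = 3). Whether the RNA libraries undercount ENST00000244534 was not tested. Its log2 fold changes were −3.86 in footprints (SE 0.13, edgeR adjusted p = 9.43e-09) and −3.14 in RNA (SE 0.22, edgeR adjusted p = 2.33e-20). The efficiency difference of −0.64 (SE 0.26, edgeR adjusted p = 0.115) did not pass the test, and it was −0.80 with adjusted p = 0.0443 in edgeR once the abundance trend was removed.

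**Figure D1:**
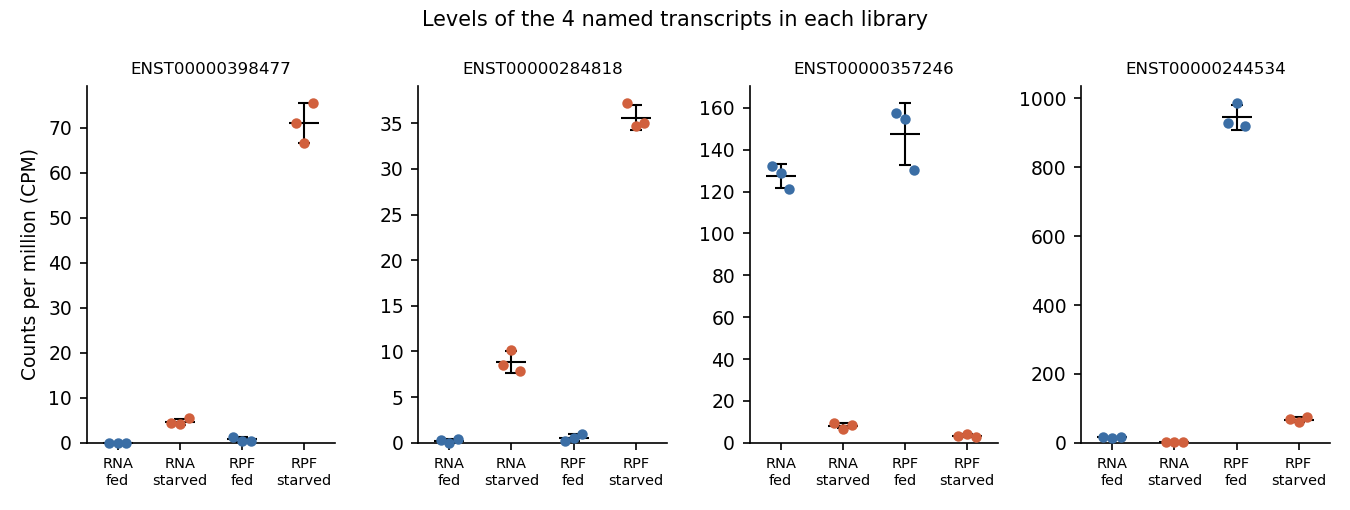
CPM (vertical axis, a separate linear scale for each panel) of the 4 named transcripts in the fed (blue) and starved (red) libraries of RNA-seq and ribosome profiling (RPF, ribosome-protected fragments); points are libraries, dashes and bars are mean and SD, n = 3. Starved and fed footprint libraries do not overlap for any of the 4, as the rule for naming required. ENST00000244534 shows 946 CPM of footprints in fed cells beside 15.6 CPM of RNA.

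Changes in RNA and in footprints mostly pointed the same way. Over the 11027 transcripts kept in both assays, the log2 fold changes correlated across transcripts with Pearson's r = 0.698 and Spearman's rho = 0.654, and 73.6% had the same sign; transcripts are not independent replicates. Both assays called 1509 transcripts higher and 2089 lower, against 679 and 944 for independent lists of the same sizes. RNA alone was called for 3772 transcripts, footprints alone for 827, and neither for 2567. The 2 assays were called in opposite directions for 263 transcripts, 119 with more RNA and fewer footprints and 144 with less RNA and more footprints, against 941 and 681 for independent lists. Among the 7148 transcripts with an average log2 CPM of at least 4 in both assays r was 0.805. The count of 263 was 166 with the Wald test of DESeq2 and 168 without fed footprint replicate 1.

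Translational efficiency was called for 2519 of 11027 transcripts (22.8%), 1227 higher and 1292 lower in starved cells, by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment. This split depended on the scaling: library totals without TMM factors gave 1567 higher and 803 lower. More than 2-fold changes were called for 577 transcripts with higher and 184 with lower efficiency, and more than 4-fold changes for 96 and 24.

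In most transcripts the RNA change came without a called change of efficiency. An uncalled efficiency need not be unchanged, since the median standard error of its log2 fold change was 0.20. This class held 5672 transcripts: 2944 whose RNA rose (median log2 fold change 0.56 in RNA and 0.41 in footprints) and 2728 whose RNA fell (−0.60 and −0.64). The next class, 1552 transcripts, had an efficiency change opposing the RNA change. Its 741 transcripts with higher RNA had a median RNA log2 fold change of 0.69 and a median footprint log2 fold change of −0.07. Its 811 transcripts with lower RNA had medians of −0.83 and 0.16. With the limit of an average log2 CPM of at least 4 in both assays, 1014 opposing and 386 following transcripts were counted. Efficiency followed RNA in 409 transcripts, 125 with medians of 0.40 in RNA and 1.03 in footprints, and 284 with −0.43 and −1.16. The count of 409 was 254 without fed RNA replicate 2 and 268 without starved RNA replicate 3. Efficiency without RNA was called for 558 transcripts, 291 with higher efficiency and a median footprint log2 fold change of 0.74, and 267 with lower efficiency and −0.71. Neither RNA nor efficiency was called for 2836.

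**Figure D2:**
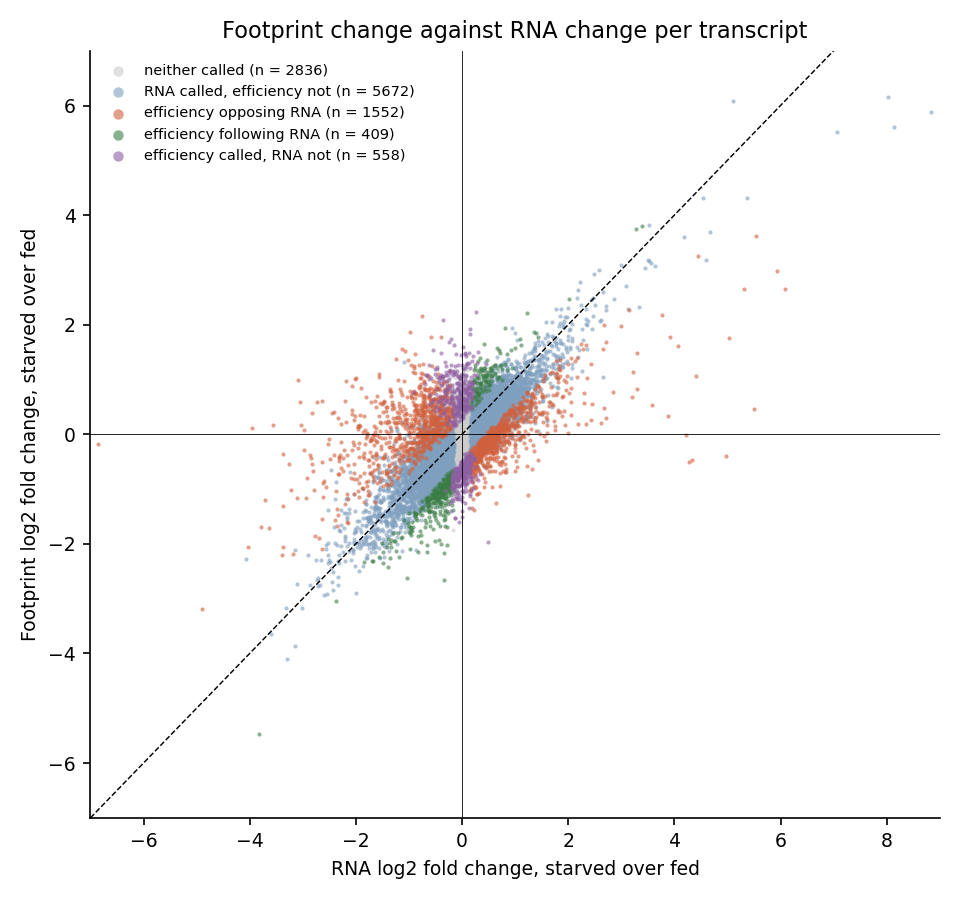
Log2 fold change of starved over fed in footprints (vertical axis) against RNA (horizontal axis). Each point is 1 of the 11027 transcripts kept in both assays, coloured by class. Red marks efficiency opposing RNA, green efficiency following RNA, and blue RNA called without efficiency. Purple marks efficiency called without RNA, and grey marks neither RNA nor efficiency called. The dashed line marks equal change. The 1552 transcripts with opposing efficiency lie between the dashed line and the horizontal axis or beyond that axis, and the 409 with following efficiency lie on the far side of the dashed line.

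With TMM factors, efficiency calls went opposite ways at the ends of the abundance range. In the bin with the least RNA, efficiency was called higher for 387 transcripts and lower for 81. In the bin with the most RNA it was called higher for 216 and lower for 548. Of the 577 transcripts with more than 2-fold higher efficiency, 344 were in the bin with the least RNA. With library totals alone the counts were 449 and 63 in the bin with the least RNA and 267 and 342 in the bin with the most. With the abundance trend removed, which centres fold changes at each level by construction, they were 198 and 171 in the bin with the least RNA and 355 and 248 in the bin with the most, where the direction turned. The slope of footprint on RNA log2 fold change across transcripts was 0.43 in the bin with the least RNA and 0.83 in the bin with the most. In 20 simulations with no change of efficiency the slopes were 0.94 and 0.99. In the bin with the least RNA the slope does not separate a change of efficiency from background footprints on weak transcripts, which stay open there.

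**Figure D3:**
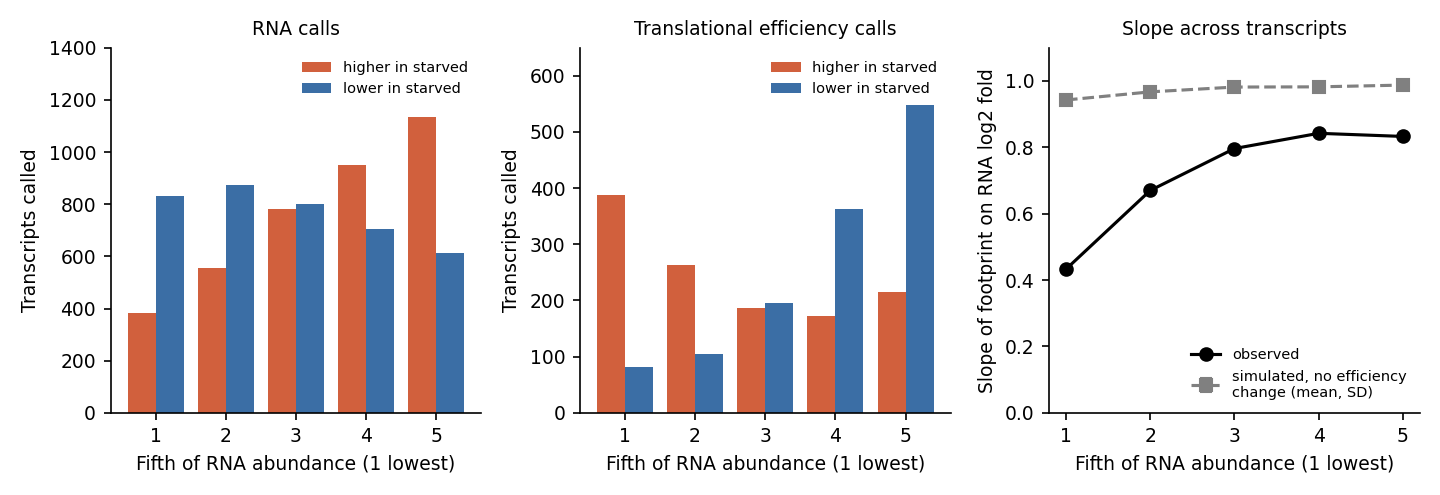
Transcripts called higher (red) or lower (blue) in starved cells for RNA (left) and translational efficiency (middle) in 5 bins of equal size by mean RNA level (horizontal axis, 1 lowest), and slope of footprint on RNA log2 fold change in each bin (right; circles observed, squares with bars mean and SD of 20 simulations without efficiency change). Efficiency calls change from 387 higher and 81 lower in the bin with the least RNA to 216 higher and 548 lower in the bin with the most with TMM factors, and from 198 and 171 to 355 and 248 with the abundance trend removed (not drawn).

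Transcripts with little or no RNA gained footprints more often than they lost them. Footprints could be tested on 2430 transcripts that did not have enough RNA counts for the RNA test; 582 rose and 89 fell, with a median log2 fold change of 0.44. Among transcripts tested in both assays, 1965 rose and 2723 fell, with a median of −0.04. With library totals alone the counts were 678 and 82 against 2216 and 2493, and with the abundance trend removed 453 and 110 against 2120 and 2614. The shares of rising and falling calls differed between these sets (Fisher's exact test over transcripts, two-sided p = 1.42e-113; transcripts are not independent replicates). Footprints on the 4632 transcripts without any RNA count, for which 3 counts over the 6 RNA libraries set a limit of 0.0753 CPM, took 2.10 ± 0.209% of footprint counts in fed and 2.60 ± 0.379% in starved libraries (SD, n = 3). This difference reached the smallest p that 3 against 3 libraries allow (exact two-sided permutation test, p = 0.1, 0.167 after Benjamini-Hochberg adjustment over 5 shares).

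The most abundant footprinted transcripts took a larger share of starved libraries. The 10 most abundant transcripts of each library took 6.09 ± 0.538% of footprints in fed and 8.29 ± 0.806% in starved libraries (SD, n = 3; exact two-sided permutation test, p = 0.1, adjusted 0.167). In RNA the same measure was 13.9 ± 0.504% and 13.7 ± 1.79% (SD, n = 3; exact two-sided permutation test, p = 0.9, adjusted 0.9). The transcript with the most RNA, 9.18% of all RNA counts, had 1.96% of footprint counts. Its log2 fold change was 0.13 in RNA (edgeR adjusted p = 0.455) and 0.75 in footprints (edgeR adjusted p = 0.00101), and its efficiency rose by 0.71 (SE 0.22, adjusted p = 0.0223, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

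**Figure D4:**
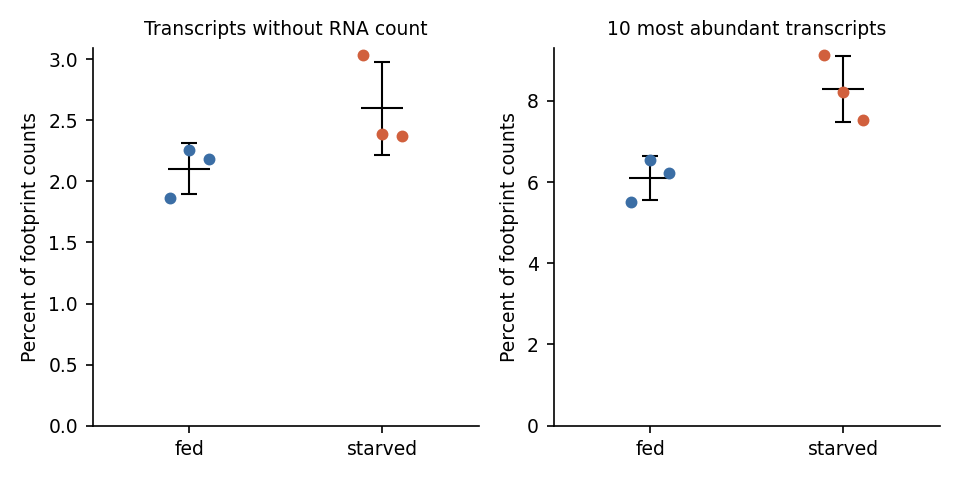
Percent of footprint counts on transcripts without any RNA count (left) and on the 10 most abundant transcripts of each library (right) in fed (blue) and starved (red) libraries; points are libraries, dashes and bars are mean and SD, n = 3. All 3 starved libraries lie above all 3 fed libraries in both panels, with starved replicate 1 the highest.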

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

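The tests chosen only after the result was seen were those of opposing and of opposite calls in the bin with the most RNA and of the footprint share without starved replicate 1; removal of the abundance trend, held-out replicates, separate RNA libraries and the other settings of the opposing and opposite counts were likewise added after the data, and these counts, had been seen.

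The same contrast went different ways in the 2 assays for 263 transcripts called in both, and the interaction of assay and treatment was called for all 263. The interaction is the difference of the 2 changes, so picking opposite calls makes its call likely, and it adds no separate support. Sampling noise would leave at most 50% of such calls with both signs in libraries not used to make them; in the worst of 3 rounds with 1 replicate number held out, 82.5% of 160 calls kept both signs. Background footprints on weak transcripts, as the whole source, would leave few opposite calls in the bin with the most RNA. That bin held 88 of the 263, beside 544 higher and 608 lower footprint calls. The bin with the least RNA held 62, beside 313 higher and 328 lower footprint calls, and background stays open there. Since the bins differ in how many calls were made, the counts of 88 and 62 do not rank them. With the abundance trend removed, 152 of the 263 (57.8%) remained called in opposite directions, so that trend may account for some of them but not for the majority. Ribosomes held on transcripts by arginine shortage, reads shared with other transcripts and footprints outside coding sequences stay open and were not tested, and the count was 166 with the Wald test of DESeq2 and 168 without fed footprint replicate 1.

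Efficiency opposed RNA in 1552 transcripts and followed it in 409, which would buffer footprints against RNA changes. Because RNA counts enter both values, noise in them alone could give such an excess; with the RNA call and the efficiency taken from different RNA libraries, opposing calls were 85.3% to 85.8% of the total in 3 rotations, each with far fewer calls (162 to 188 opposing, 28 to 31 following) and with 1 RNA library per group in the efficiency model, assumed to vary like the footprint libraries. The 20 simulations with no change of efficiency gave at most 1 opposing and 0 following calls each. With no true change the adjusted threshold passes almost no calls. The simulations therefore do not show how noise splits calls where many pass. As far as simulated noise matches the real noise, noise alone gave too few calls to make up the 1552. The 3 rotations, within their limits, argue against noise as the whole source of the excess. In the bin with the most RNA 440 opposed and 171 followed, which argues against background on weak transcripts as the whole source. That background stays open in the bin with the least RNA, with 353 against 6. With the abundance trend removed 1283 opposed and 346 followed, and with an average log2 CPM of at least 4 in both assays 1014 and 386. A compressed range of the footprint assay and a regulated response of translation to arginine were not separated by these data.

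Among transcripts without any RNA count, 972 had a mean footprint count of at least 10 per library, a signal outside the RNA and efficiency comparisons; of the 908 with a footprint test, 223 rose and 31 fell, with a median log2 fold change of 0.45. A uniform background of fragments would change all of them by the same factor. Scaled to their own total, 82 of the 972 were called (8.44%, 95% exact interval 6.77 to 10.4%), 34 higher and 48 lower. This scaling centres the set, so the near balance of 34 and 48 is by construction. Most of the 972 were not called, at a median of 20.3 footprint counts per library, and a uniform background stays open for those. The higher share in starved libraries could rest largely on starved replicate 1, at 3.04% against 2.39% and 2.37% in the others; without it the lowest starved library lay 0.112 percentage points above the highest fed library, less than the SD of fed libraries, and this cannot be told apart from a real difference with so few libraries. RNA without a poly(A) tail and reads from near-identical transcripts were not tested, and 4 of the 972 had counts identical to another transcript.

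The footprint table listed 163 transcripts that the RNA table did not, with a median total of 34 counts and 0.0775% of footprint counts.

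With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 7862 RNA, 5359 footprint and 2519 efficiency calls and was the only 1 of the 10 to give as many in each of the 3 comparisons. The highest count of any other split was 0 in edgeR in each, with at most 93, 286 and 134 transcripts at an unadjusted p under 0.05, where the real split had 8105, 6580 and 3890. Every other split puts fed and starved libraries in the same group, so the treatment difference enters the spread and few calls follow. Their low counts therefore do not test the real split.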

How the results depend on the processing

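The settings with the abundance trend removed, with RNA thinned, with transcripts kept in both assays and, for efficiency and for opposing and opposite calls, with an expression limit were chosen only after the results were seen, as were the counts of opposing and opposite calls themselves. The counts of RNA, footprint and efficiency calls stayed within 1.5 times their value in every alternative run. Leaving out 1 library gave 7324 to 7680 RNA calls, 4157 to 5072 footprint calls, 1905 to 2538 efficiency calls, 1206 to 1575 opposing calls, 254 to 421 following calls, 168 to 248 opposite calls and r of 0.677 to 0.706. The following count, 409 with all libraries, was 254 without fed RNA replicate 2 and 268 without starved RNA replicate 3. The opposite count of 168 came without fed footprint replicate 1, and it was 166 with the Wald test of DESeq2; the cause was not tested. With an average log2 CPM of at least 4 in both assays r was 0.805 and opposing calls were 1014 beside 386 following, from fewer transcripts. The split of footprint calls moved to 2894 higher and 2575 lower with library totals and to 2353 and 2920 without a filter on low counts, that of RNA calls to 3189 and 4677 with library totals. The split of efficiency calls moved to 1567 higher and 803 lower with library totals and to 1032 and 1705 without a filter on low counts. Of the values of named transcripts under these alternatives 187 kept their direction and side of the threshold, 1 passed it (ENST00000244534 efficiency, −0.80 with the trend removed) and 1 reversed (ENST00000398477 efficiency, 0.29 with limma-voom); the cause was not tested. Replicate numbers showed no consistent pairing of the libraries. Deviations of same-numbered libraries correlated between −0.25 and 0.29, and 2 of 6 RNA libraries matched best the footprint library of their own number. With 3 libraries per group these values cannot exclude a pairing. The replicate block gave 7956 RNA, 4656 footprint and 2306 efficiency calls, and the culture term 2494 efficiency calls. RNA thinned to footprint depth still gave 6591 calls, so depth alone does not set the lower footprint count. The 26 gene lists and the arginine codon comparison, with their alternatives, were not run for lack of gene names.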

Other observations

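A set of transcripts had a far higher footprint level than RNA level. RNA without a poly(A) tail, reads shared with other transcripts and footprints outside coding sequences were not tested as reasons. Of the transcripts with an average footprint log2 CPM of at least 4, 808 had a footprint level at least 16 times their RNA level (with RNA set to no less than 3 counts over the 6 libraries). These 808 took 13.4% of footprint counts and 0.170% of RNA counts. Their footprints rose on 246 and fell on 127, while the other 7872 transcripts above the same level had 1574 that rose and 2234 that fell (Fisher's exact test over transcripts, two-sided p = 8.05e-20; transcripts are not independent replicates). RNA was tested for 163 of the 808, and it rose for 21 and fell for 68. Of the other 7872, RNA was tested for 7866. The rest of the 808 are among the 2430 transcripts without an RNA test described above. This contrast therefore largely repeats the earlier one and is not separate support for it. Although more of them rose than fell, their summed share of footprints lay between 13.8% and 16.3% in the fed and between 11.2% and 13.9% in the starved libraries, which overlap. With library totals alone 275 rose and 124 fell, and with the abundance trend removed 265 and 117. The set was defined after the data were seen.

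The 4 transcripts with the most RNA behaved alike. None was called in RNA, with log2 fold changes between −0.12 and 0.13, and each was called higher in footprints (0.52 to 0.75) and in efficiency (0.66 to 0.82) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The footprint calls of all 4 were also made with DESeq2 size factors, with library totals and with the abundance trend removed; in the last, efficiency was called higher for 2 of the 4 and RNA was called for 1. These were also chosen after the data were seen.

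Some footprint counts dropped out of a single library. A level more than 8-fold below the mean of the other libraries of the group, each with at least 50 counts, was seen for 21 transcripts in footprints and 0 in RNA, and 10 of the 21 were in starved replicate 3 and 7 in fed replicate 2.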
